A study of Clostridium acetobutylicum with 8 samples.

How the data were processed

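RNA from Clostridium acetobutylicum cultures was labelled with a single dye and hybridised to 8 Agilent arrays, 2 for each of 4 groups: an overexpression strain for btrK and btrR and a control strain, at 24 h and 48 h. Groups and replicate numbers were taken from the sample titles. The deposited scanner files hold an intensity for each of 15517 spots, background-corrected in the processed signal by Agilent Feature Extraction, version 12.0.3.1 per the file headers, while the submitters' processing notes name another version. The authors also deposited a table of log2 values for 3798 of the 4077 probes; their normalization and centring are not given in the sources used here. Each column of that table correlated with the processed signal of the same array at r of 0.9978 to 0.9993 and with other arrays at no more than 0.9924, and its slope against the log2 signal was 0.967 to 1.014, so its scale is log2 and its rows were matched by probe name. The table's column medians were 7.94 and 7.91 for overexpression 24 h replicates 1 and 2, 7.95 and 7.90 for overexpression 48 h, 7.94 and 7.88 for control 24 h, and 7.92 and 7.91 for control 48 h.

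Of the 15517 spots, 14981 were not controls. They held 4077 probes, no pair of which shared a name: 3627 with CAC tags, 171 with CA_P tags of the megaplasmid, 229 with CEA tags and 50 with no gene name. A probe with a tag was taken to stand for 1 gene. The unnamed probes were printed 58 times each and the other 4027 probes 3 times. The unnamed probes thus took 2900 of the 14981 non-control spots and weigh on the array percentile and median used for centring below. The 229 CEA probes and 50 unnamed probes are the 279 that the authors' table lacks. The files give no product description, so the function of no gene could be checked against an annotation, and the functions mentioned are textbook background.

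The measured value of a spot was log2 of the processed signal minus the log2 of the array's 75th percentile over non-control spots. Spots with an outlier flag, 1.56% to 2.86% of an array's spots, were left out unless all spots of the probe had one, and the remaining spots of a probe were averaged. The median coefficient of variation over spots of a probe was 3.57% to 9.32%. Probes well above background on both arrays of at least 1 group were tested, which left 3859. A probe not well above background on any array of a group has only a bound there, given as "at least N-fold": the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

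Differences between groups were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) in a model with 1 mean for each of the 4 groups, 4 residual degrees of freedom and 3.42 prior degrees of freedom, two-sided, with Benjamini-Hochberg adjustment over the features tested in each contrast. The contrasts were overexpression against control at 24 h and at 48 h, the difference between these strain effects, and 48 h against 24 h in each strain. A feature was called at an adjusted p under 0.05 and a change of at least 2-fold, the limit that the series' design text states. The script was tested on simulated data for the comparison at 24 h over 3859 genes: of 50 genes each given log2 changes of 1.5, 2, 3 and 5, the test called 94%, 96%, 96% and 100%, with 0 false calls. For the comparison at 48 h over 3859 genes, a simulated list of 12 genes shifted by 1 log2 unit passed limma's camera test. An unchanged list of 12 did not. The simulated noise was normal, with the spread that the fit had estimated, and no departure of a whole array was added. The simulation therefore tests the script and does not give the rate of false calls on these arrays. The simulated genes varied independently, so lists of correlated genes were not covered. Estimated correlations within the lists tested below reached 0.975, for histidine synthesis.

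Before the data were examined, 30 gene lists were fixed, 166 members of them by locus tag, of which 28 were not on the array under that tag. Lists with at least 3 measured members were tested with limma's camera at a correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and also with an estimated correlation and with limma's fry. Of the 30 lists 17 could be tested. The other lists were 3 with fewer than 3 measured members (acetate and butyrate formation and acetyl-CoA to butyryl-CoA with 2 each, glycolysis with 1) and 10 defined by product descriptions that were not used here, such as flagella, ribosomal proteins and ABC transporters.

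The genes named were chosen by a rule fixed before the data were examined: in each strain comparison the 6 called genes with the largest rise and the 6 with the largest fall, among genes whose overexpression arrays both lay on the same side of both control arrays and which were well above background on both arrays of the brighter group; from each list the called member with the largest rise and the one with the largest fall; the members of solvent formation, acetate and butyrate formation and early sporulation regulators in any case; and the 6 largest rises and falls with age in the control strain. A part of the rule on two-component genes could not be applied, since no annotation names them, and the files do not pair btrK or btrR with a locus tag.

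The alternatives were quantile normalization, centring on the array median, normexp background correction with an offset of 50 on the mean and background signals, no filter on dim probes, only probes above background on all 8 arrays, the replicate number as a block, a fit on only the 4 arrays compared, eBayes with trend and robust, calls by adjusted p alone or by 2-fold alone, the authors' table, and leaving out each of the 8 arrays in turn. After the data were seen, 3 more were added: only CAC and CA_P features, the authors' table with 2-fold alone, and centring on the spike-in probes (7 probes). Using the brightest probe of a gene was not run because each gene name has 1 probe, and a slide or scan block was not run because all arrays share 1 slide and 1 scan.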

Results

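Gene expression was measured with one-colour Agilent arrays in Clostridium acetobutylicum, a spore-forming anaerobe that makes acetone, butanol and ethanol. A strain overexpressing btrK and btrR, which the series title names as a two-component system, was set against a control strain after 24 h and 48 h of fermentation on glucose. Each of the 4 groups held 2 arrays, 8 in all. The arrays held 4077 features, of which 3859 were well above background on both arrays of at least 1 group and were tested. Between 88.6% and 95.2% of the features were well above background on an array, and the median processed signal ranged from 155.4 in control 24 h replicate 1 to 436.2 in overexpression 48 h replicate 1. No spot was saturated. The number of arrays limits the precision of every value below, and nothing in the labels says that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between arrays, which may be technical. Levels are log2 signals relative to the array's 75th percentile and changes are differences of their group means, with the SE of the limma fit.

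The control 24 h arrays stood apart from the other 3 groups. On the first principal component, which held 49.1% of the variance, they scored 39.01 and 46.33, while the other 6 arrays lay between -31.95 and 1.56. The mean correlation across genes of overexpression 24 h arrays was 0.971 with control 48 h arrays and 0.932 with control 24 h arrays. Replicate arrays correlated at 0.9816 in control 24 h, 0.9872 in control 48 h, 0.9925 in overexpression 24 h and 0.9868 in overexpression 48 h, and the number of features differing at least 2-fold between replicates was 225, 97, 65 and 171 in that order. All 8 arrays lay on 1 slide, with each group in its own pair of neighbouring places, so that the place on the slide and the group cannot be told apart.

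**Figure D1:**
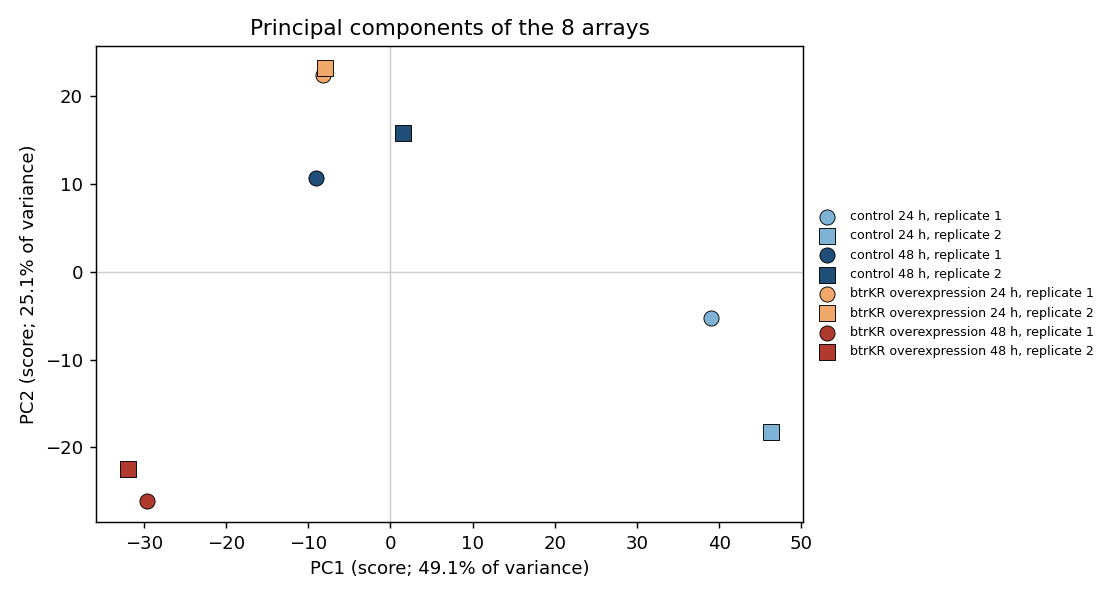
Scores of the 8 arrays on the first 2 principal components of the 3859 tested features; each point is 1 array, the colour gives the group and the marker the replicate. The control 24 h arrays lie at 39.01 and 46.33 on the first component, to the right of the other 6.

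The first comparison set the overexpression strain against control at 24 h, to find genes whose expression follows btrK and btrR. The largest rises were those of CAC0860 and CAC0863, 925-fold and 1270-fold. CAC0860 was at 6.36 ± 0.060 (SD, n = 2) in the overexpression strain and -3.49 ± 0.251 in control, and CAC0863 at 6.42 ± 0.040 and -3.89 ± 0.210. Their log2 changes were 9.85 ± 0.211 (SE; adjusted p = 7.49e-07) and 10.31 ± 0.293 (SE; adjusted p = 3.05e-06), and under normexp background correction the latter was 9.25. CAC0861 and CAC0862, the tags numbered between them, rose by 2.99-fold and 2.13-fold. Outside the pair CAC0858, CAC0859, CAC0866 and CAC0867 were also called, at 3.15-fold, 3.14-fold, 3.06-fold and 2.26-fold. CAC0857, CAC0864 and CAC0865 were below 2-fold. These neighbouring tags were chosen after their values were seen. The files do not pair locus tags with btrK or btrR, so the overexpressed genes themselves could not be read out by name. Further large rises were those of CAC0608 (10.4-fold), the potassium transport genes CAC3680 and CAC3681 (9.84-fold and 9.3-fold) and the megaplasmid gene CA_P0102 (9.06-fold), with adjusted p between 0.000388 and 0.000619. The largest falls were those of CAC2389 and CAC2388 of arginine synthesis (15.5-fold and 11.1-fold), CAC2951 and CAC3618 (11.2-fold each), CAC2645 of carbamoyl phosphate synthesis (a log2 change of -3.41) and CAC1133. CAC1133 was not well above background on either overexpression array and was at least 8.07-fold lower there (adjusted p = 0.00515); this bound sets the mean of the brighter group against the lowest signal among probes well above background on the dim arrays, or the probe's own where higher. Under normexp background correction its change was -0.46 and did not pass.

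**Figure D2:**
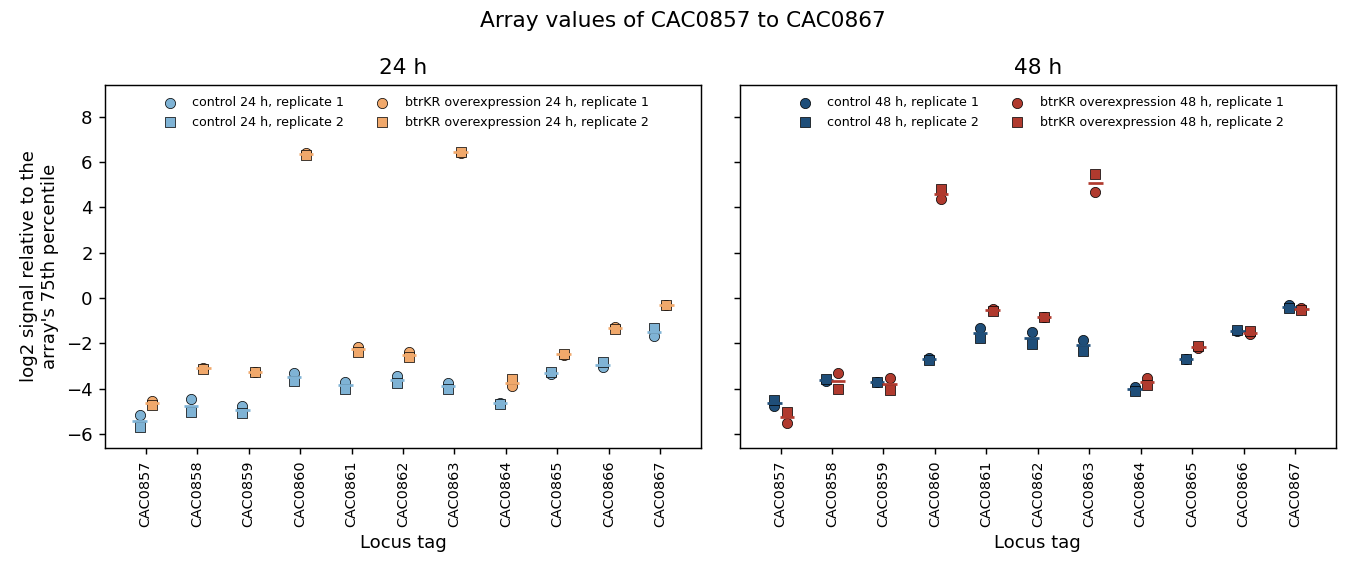
Array values of the 11 features from CAC0857 to CAC0867 at 24 h (left) and 48 h (right), as log2 signal relative to the array's 75th percentile; each point is 1 array and each bar a group mean of 2 arrays. CAC0860 and CAC0863 lie at group means of 6.36 and 6.42 in the overexpression strain at 24 h, while CAC0861 and CAC0862 between them lie at -2.27 and -2.51.

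At 24 h 1027 features were called, at an adjusted p under 0.05 with at least a 2-fold change, 619 higher and 408 lower. The split into higher and lower depended on the scaling: centring on the median gave 371 higher and 621 lower, and centring on spike-in probes, an alternative chosen after the data were seen, 845 and 319. The median change over all tested features was 0.17 with the 75th percentile and -0.10 with the median, a shift against which each change below can be read. Without control 24 h replicate 2 the count was 797, and under normexp background correction it was 326.

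Several lists of amino acid and purine synthesis were lower than other genes in the overexpression strain at 24 h. Tryptophan synthesis was not among them (0 of 7 called, camera adjusted p = 0.661). The comparison of 48 h with 24 h in control shares the control 24 h arrays. There the branched-chain, arginine, purine and histidine lists were also lower (camera adjusted p = 0.00138, 0.0153, 0.0299 and 0.0299). The sulfate and cysteine list did not pass there (0.38). Of 6 measured members of branched-chain amino acid synthesis, 5 fell, CAC3171 the most (4.36-fold; adjusted p = 0.000709), and the list was lower than other genes (camera adjusted p = 0.000452). Of 9 measured members of arginine synthesis, 8 fell (median of the list -3.09; camera adjusted p = 0.00567), and of 7 of purine synthesis 5 fell (camera adjusted p = 0.00394), CAC1394 the most, 6-fold. Of 9 histidine synthesis genes 4 fell, with CAC0938 at -1.36 ± 0.425 (SE; adjusted p = 0.0321; camera adjusted p = 0.0102). The 9 sulfate and cysteine assimilation genes had a median change of -2.92 and a camera adjusted p of 0.0144, and none of them passed the gene test. Adjusted over the list alone, 5 branched-chain, 8 arginine, 6 purine and 0 histidine genes fell. With an estimated correlation none of these 5 lists passed (adjusted p = 0.614 with an estimated correlation for each). The control 24 h arrays differed widely in arginine genes, with SDs of 2.26 for CAC2388 and 2.03 for CAC2389, and without control 24 h replicate 2 both lost their calls (log2 changes -1.88 and -2.52, adjusted p = 0.172 and 0.12), while without control 24 h replicate 1 they were at -5.07 and -5.39. Leaving out either overexpression 24 h array also ended both calls, at adjusted p from 0.0734 to 0.123, as did leaving out control 48 h replicate 1 for CAC2388 (adjusted p = 0.0502). The histidine list was lost without control 24 h replicate 2 (camera adjusted p = 0.0647), as was CAC0938 (adjusted p = 0.144), whose call also ended without overexpression 24 h replicate 1 or 2 (adjusted p = 0.103 and 0.112). The sulfate and cysteine list was lost without control 24 h replicate 1 (camera adjusted p = 0.0514) and after centring on the median (0.0654). Under normexp CAC0938, CAC2388 and CAC2389 lost their calls (adjusted p = 0.122, 0.126 and 0.115), the last 2 also with a trended and robust prior (0.113 and 0.0854) and CAC0938 also with spike-in centring (0.0597). By fry, which asks whether the genes of a list move 1 way rather than comparing them with other genes, the branched-chain list passed (adjusted p = 0.00584), while the purine, arginine, histidine and sulfate lists did not (0.0591, 0.112, 0.204 and 0.22).

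The lists of oxygen and peroxide defence and fatty acid synthesis were lower than other genes at 24 h. Both were also lower with age in control, which shares the control 24 h arrays (camera adjusted p = 0.00138 for each). Of 7 oxygen and peroxide defence genes, 4 fell, among them CAC2449, a flavoprotein gene, by 2.95-fold (adjusted p = 0.00348), and the list had a median change of -1.15 (camera adjusted p = 0.00352). Of 12 fatty acid synthesis genes 1 fell, CAC3575 by 2.03-fold (adjusted p = 0.00415), and the list had a median of -0.35 (camera adjusted p = 0.0149). The same numbers fell adjusted over the list alone, 4 and 1, and neither list passed with an estimated correlation (adjusted p = 0.614 with an estimated correlation for both). The fatty acid list was lost without overexpression 24 h replicate 2 (camera adjusted p = 0.118) or control 24 h replicate 2 (0.0501), and CAC3575 changed less than 2-fold without either, at -0.85 and -0.88, and with quantile normalization (-0.96), the authors' values (-0.98), normexp (-0.96) and spike-in centring (-0.86). By fry the oxygen list passed (adjusted p = 0.0411) and the fatty acid list did not (0.109).

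The agr quorum sensing genes rose in the overexpression strain at 24 h, and the phosphate uptake list was higher than other genes. With age in control, which shares the control 24 h arrays, the phosphate list was also higher (camera adjusted p = 0.00138). The agr list did not pass there (0.156). All 4 measured agr genes rose, with a median of 2.01 (camera adjusted p = 0.0255); CAC0078 rose by 5.85-fold (adjusted p = 0.00623), a log2 change of 2.55 that was 3.33 and 1.77 without control 24 h replicate 1 or 2. Of 7 phosphate uptake genes 3 rose, with a median of 1.00 (camera adjusted p = 0.0285), and CAC1705, the phosphate-binding protein gene, rose by 3.12-fold (adjusted p = 0.00157). Adjusted over the list alone the counts were also 4 and 3. Neither passed with an estimated correlation (adjusted p = 0.614 with an estimated correlation for both). By fry both lists passed (adjusted p = 0.0108 for agr and 0.00584 for phosphate). The phosphate list was lost without overexpression 24 h replicate 2 (camera adjusted p = 0.059), without control 24 h replicate 1 (0.0621) and under normexp background correction (0.115), under which CAC1705 also lost its call (a change of 0.92; adjusted p = 0.105).

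In solvent formation 4 of the 8 listed genes were measured. Among them CA_P0165, acetoacetate decarboxylase, rose by 3.25-fold at 24 h (2.30 ± 0.047 in the overexpression strain and 0.60 ± 0.253 in control, SD, n = 2; adjusted p = 0.000833). CA_P0164, a subunit of the CoA transferase of acetone formation, rose by 2.91-fold (adjusted p = 0.00693). Its partner CA_P0163 had a change of 0.02 ± 0.258 and CAC3392 one of 0.67 ± 0.198 (SE). Both acetate formation genes measured, CAC1742 and CAC1743, had changes of 0.95 and 0.87 with adjusted p of 0.00709 and 0.00519, below the 2-fold limit; without control 24 h replicate 2 they passed it, at 1.04 and 1.00. They also passed it after centring on spike-ins, as did CAC2071 and CAC2859 below. The glycolytic enzyme CAC3657, a non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase, fell by 2.84-fold (adjusted p = 0.00218).

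Of 12 early sporulation regulators measured at 24 h, 3 were called. CAC2307 and CAC2308 of the sigF operon rose by 2.06-fold and 2.22-fold (adjusted p = 0.0185 and 0.0178) and CAC3205, spoIIE, fell by 2.64-fold (adjusted p = 0.00306). The sigF operon calls were below 2-fold or lost with quantile normalization, median centring, the authors' value table and normexp. They also ended without overexpression 24 h replicate 1 (adjusted p = 0.073 and 0.0766), without overexpression 24 h replicate 2 (0.0814 and 0.0709) and without control 24 h replicate 2 (0.09 and 0.0873). The master regulator gene spo0A, CAC2071, was at 0.88 ± 0.223 (SE; adjusted p = 0.0144), short of 2-fold, and reached 1.02 without control 24 h replicate 1. The third gene of the sigF operon, CAC2306, had a change of 0.74 and reached 1.06 without that array. CAC1689 (sigK) had a change of -0.97 and CAC2859 (spoIIID) one of 0.85, both at an adjusted p under 0.05; CAC1689 passed the 2-fold limit, at -1.24, with median centring, and also with quantile normalization, the authors' value table, and without control 24 h replicate 1 or overexpression 24 h replicate 2 (-1.23 and -1.14). CAC1694, CAC1695 and CAC1696 of the sigE and sigG genes had changes of 0.14, 0.55 and 0.32, CAC0310 (abrB) one of 0.30 and CAC3152 (sigH) one of -0.00, none of which passed. Neither sporulation regulators nor solvent formation passed as a list (camera adjusted p = 0.628 and 0.153), and adjusted over the list alone 3 and 2 members were called. Solvent formation passed under normexp (camera adjusted p = 0.0403) and by limma's fry (adjusted p = 0.0411).

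Among 16 heat shock and protein quality control genes at 24 h, 2 rose, CAC2433, an HtrA-type protease gene, by 3.58-fold (adjusted p = 0.00165); the list's camera adjusted p was 0.0796. The list passed with quantile normalization (0.0268), under normexp (0.0125), without control 24 h replicate 2 (0.028) and by fry (adjusted p = 0.0411). Of 163 megaplasmid genes 25 rose and 20 fell, the largest fall being that of CA_P0128, 5.9-fold (adjusted p = 0.000574; a change of -1.93 under normexp instead of -2.56), and the list did not pass (camera adjusted p = 0.704). The lists of pyruvate and hydrogen, ATP synthase, tryptophan synthesis and cellulosome had no called member and camera adjusted p of 0.316, 0.511, 0.661 and 0.704. The pyruvate and hydrogen list had a median of 0.04, a mean of -0.23 and a camera direction of down, and its median turned to -0.23 with median centring.

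At 48 h the question was the same in older cultures, and the strains differed in 494 features. CAC0860 and CAC0863 were again the largest rises, 155-fold and 142-fold, at 4.59 ± 0.329 and 5.05 ± 0.564 (SD, n = 2) in the overexpression strain against -2.69 ± 0.063 and -2.09 ± 0.349 in control. Their log2 changes were 7.28 ± 0.211 and 7.15 ± 0.293 (SE; adjusted p = 7.03e-06 and 4.51e-05), and CAC0861 and CAC0862 had changes of 0.99 and 0.94, below the 2-fold limit. CAC3362 rose by 7.98-fold (adjusted p = 0.000327) and the megaplasmid gene CA_P0058 by 7.01-fold (adjusted p = 0.00126), and both lost their calls under normexp background correction, at changes of 0.58 and 1.68. CAC1109 and CAC1133 were not well above background on either control 48 h array and were at least 6.17-fold and 6.15-fold higher in the overexpression strain (adjusted p = 0.0199 and 0.0226). Their 2 overexpression arrays differed, with SDs of 1.74 and 1.58. Their changes, 2.99 and 2.88, were 1.76 each without overexpression 48 h replicate 1, and that of CAC1109 was 4.22 without overexpression 48 h replicate 2, so the folds depend on single arrays. Under normexp both changes were negative (-0.54 and -0.67), near the median of -0.49 over all tested features, and neither passed. CAC1109 did not pass in the fit of only the 4 arrays compared (adjusted p = 0.0572). It also lost its call without control 48 h replicate 1 (adjusted p = 0.0919) or 2 (0.0656), and CAC1133 without control 48 h replicate 1 (0.0726) or 2 (0.115) or overexpression 48 h replicate 1 (0.0538).

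Of the 494 features called at 48 h, 106 were higher and 388 lower. The split again depended on the scaling, with 208 higher and 294 lower after centring on the median, 195 and 272 with quantile normalization, 154 and 260 from the authors' value table and 464 and 189 after centring on spike-ins. The median change over all tested features was -0.15 with the 75th percentile and 0.06 with the median. The number higher also depended on single arrays: it was 55 without control 48 h replicate 2, where the total was 292, and 162 without overexpression 48 h replicate 2.

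The tryptophan synthesis genes fell as a block at 48 h. All 7 measured members fell, with changes from -4.92 to -4.06 on the log2 scale, and adjusted over the list alone 7 also fell. The list was lower than other genes (camera adjusted p = 0.00475), but did not pass by fry (adjusted p = 0.114). CAC3157 fell by 30.4-fold (-4.92 ± 0.719, SE; adjusted p = 0.00361), CAC3158 by 24.2-fold (adjusted p = 0.00749) and CAC3160, CAC3162 and CAC3163 by 24.7-fold, 24.9-fold and 26.8-fold (adjusted p = 0.03, 0.0383 and 0.036). CAC3617, outside the list, fell by 26.9-fold (adjusted p = 0.0113), and CA_P0077 of the megaplasmid by 21.7-fold (adjusted p = 0.000525). With an estimated correlation the tryptophan list did not pass (adjusted p = 0.846 with an estimated correlation), and it was lost without overexpression 48 h replicate 1 (camera adjusted p = 0.0514). Without that array the changes of CAC3157, CAC3158, CAC3160, CAC3162 and CAC3163 shrank to between -3.96 and -3.35, and without overexpression 48 h replicate 2 they were between -6.00 and -5.60, so each fold depends on single arrays. Without the former array CAC3160, CAC3162, CAC3163 and CAC3617 also lost their calls (adjusted p = 0.134, 0.167, 0.158 and 0.0592), likewise without control 48 h replicate 2 (0.14, 0.168, 0.165 and 0.075), while the first 3 did so without control 48 h replicate 1 (0.087, 0.103 and 0.0957). None of the 4 passed under normexp (adjusted p = 0.144, 0.156, 0.15 and 0.0789) or with a trended and robust prior (0.104, 0.122, 0.116 and 0.0549).

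Heat shock and protein quality control was lower than other genes as a list at 48 h. Of 16 members 7 fell and 9 were not called. As many fell when adjusted over the list alone, and the list had a median of -0.87 (camera adjusted p = 0.000817; adjusted p = 0.846 with an estimated correlation). By fry the list passed (adjusted p = 0.042). CAC3190 fell by 3.24-fold (adjusted p = 0.00538).

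Branched-chain, arginine and purine synthesis, which were lower as lists at 24 h, were higher than other genes at 48 h, with few single genes called. Histidine synthesis and sulfate and cysteine assimilation did not pass. Branched-chain amino acid synthesis had a median of 0.81 with 1 of 6 members called, CAC3174 at 2.11-fold (adjusted p = 0.0164; camera adjusted p = 0.00461). Arginine synthesis had a median of 1.43 (camera adjusted p = 0.0324) and purine synthesis one of 0.90 (camera adjusted p = 0.00647), with no called member in either. Adjusted over the list alone 1 branched-chain, 0 arginine and 0 purine genes rose. The agr genes had a median of 1.16 (camera adjusted p = 0.00475), and 1 of 4 rose, CAC0078 by 3.77-fold (adjusted p = 0.0342), or 2 adjusted over the list alone. None of these 4 lists passed with an estimated correlation (adjusted p = 0.846 with an estimated correlation for each). By fry none of the 4 passed either (adjusted p = 0.101 for branched-chain, 0.542 for arginine, 0.313 for purine and 0.0897 for agr). Their estimated correlations were 0.706, 0.82, 0.916 and 0.58 in that order, against the preset 0.01. The arginine list was lost with quantile normalization (camera adjusted p = 0.231), median centring (0.19) and without overexpression 48 h replicate 1 (0.348), and the purine list with quantile normalization (0.0643), median centring (0.0538) and without overexpression 48 h replicate 2 (0.062). CAC3174 lost its call without overexpression 48 h replicate 2 (adjusted p = 0.0788) or control 48 h replicate 2 (0.123), and CAC0078 without any of 5 arrays: overexpression 48 h replicate 1 (adjusted p = 0.141) or 2 (0.0738), control 48 h replicate 2 (0.2) and overexpression 24 h replicate 1 (0.0569) or 2 (0.0582). Under normexp neither CAC3174 nor CAC0078 passed (adjusted p = 0.103 and 0.115), CAC3174 was below 2-fold with the authors' values (0.99), and CAC0078 did not pass with a trended and robust prior (0.0711).

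**Figure D3:**
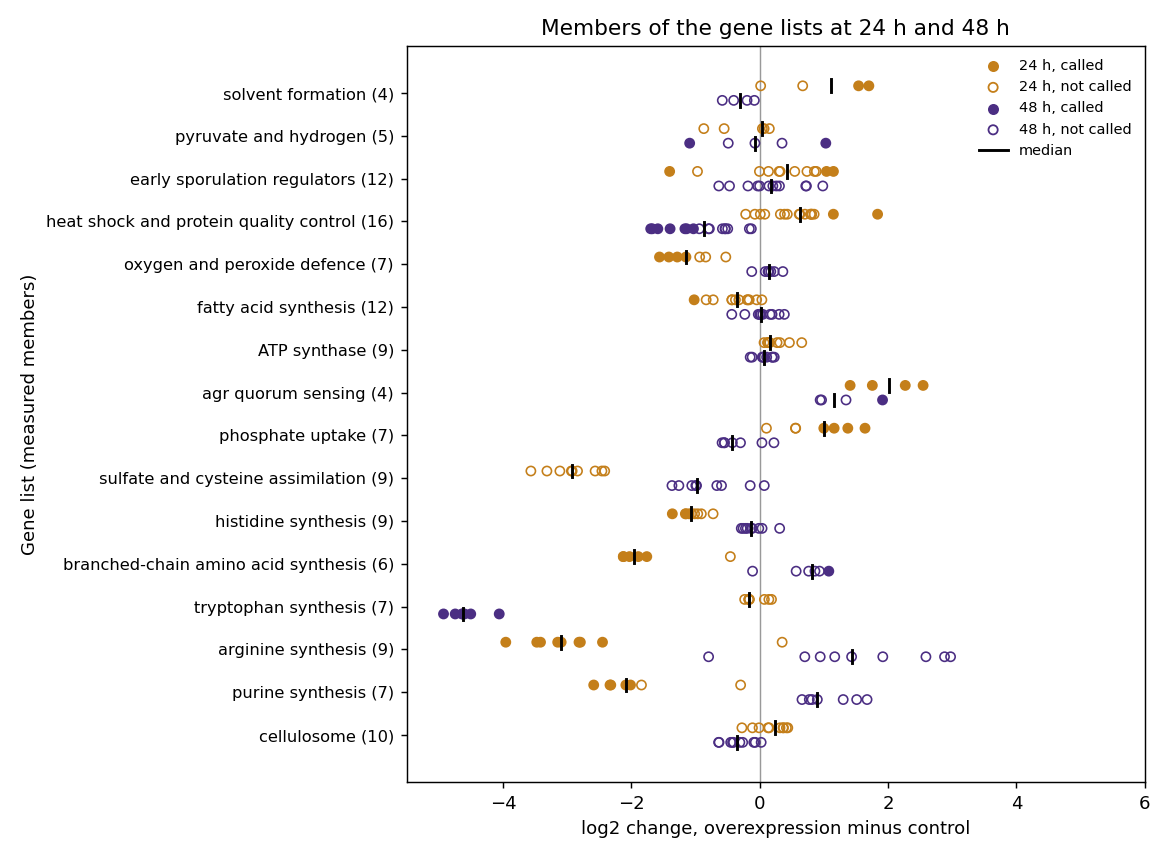
Log2 change between the overexpression and control strains for each measured member of 16 gene lists at 24 h and 48 h, each point 1 gene, filled where the gene was called, with the list median as a bar; the megaplasmid list is left out. Arginine synthesis had medians of -3.09 at 24 h and 1.43 at 48 h, and tryptophan synthesis medians of -0.16 and -4.63; the tryptophan median at 24 h turned to 0.02 with quantile normalization.

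None of the 4 measured solvent formation genes, out of 8 in the fixed list, was called at 48 h: CA_P0163, CA_P0164, CA_P0165 and CAC3392 had changes of -0.40, -0.58, -0.20 and -0.08, and CAC1742 and CAC1743 of acetate formation had changes of 0.29 and 0.10. None of the 12 early sporulation regulators was called either in the limma test. CAC1694 had a change of 0.98, CAC1695 one of 0.72, CAC2308 one of 0.73, CAC1689 one of -0.64, CAC2071 one of -0.47, CAC2307 one of 0.31, CAC3205 one of 0.26, CAC1696 one of 0.21, CAC3152 one of -0.18, CAC0310 one of 0.15, CAC2859 one of -0.03 and CAC2306 one of 0.00. Without control 48 h replicate 1, CAC1694 and CAC2308 passed, at 1.58 and 1.20, and the list was higher than other genes (camera adjusted p = 0.0155). Both genes also passed after centring on spike-ins. In the pyruvate and hydrogen list CAC0028, the hydrogenase gene hydA, rose by 2.04-fold (adjusted p = 0.0142) and CAC2499, pyruvate ferredoxin oxidoreductase, fell by 2.13-fold (adjusted p = 0.0335). CAC0028 lost its call without overexpression 48 h replicate 1 (adjusted p = 0.052) or control 48 h replicate 2 (0.11), and CAC2499 without any of 5 arrays (both overexpression 24 h arrays, overexpression 48 h replicate 2 and both control 48 h arrays), at changes of -0.77 to -1.31 and adjusted p of 0.0539 to 0.203. The change of CAC2499 was below 2-fold with quantile normalization (-0.66), median centring (-0.88), spike-in centring (-0.60) and the authors' values (-0.75), and it did not pass in the fit of only the 4 arrays compared (adjusted p = 0.0543). Under normexp neither CAC2499 (adjusted p = 0.258) nor CAC0028 (0.11) passed. Of 163 megaplasmid genes 8 rose and 25 fell, and 8 and 28 adjusted over the list alone. The lists that did not pass at 48 h were solvent formation (camera adjusted p = 0.619), pyruvate and hydrogen (0.557), sporulation regulators (0.317), oxygen and peroxide defence (0.362), fatty acid synthesis (0.382), ATP synthase (0.362), phosphate uptake (0.504), sulfate and cysteine assimilation (0.923), histidine synthesis (0.768), cellulosome (0.362) and the megaplasmid (0.224). Without control 48 h replicate 1 the histidine, sulfate and megaplasmid lists passed, as higher, lower and lower (camera adjusted p = 0.0044, 0.0438 and 0.0402), and without control 48 h replicate 2 the histidine list passed as lower (0.0125). Under normexp the ATP synthase, fatty acid, oxygen and megaplasmid lists passed (0.00637, 0.013, 0.0105 and 0.0328). Median and camera direction differed in sign for histidine synthesis (-0.13) and for pyruvate and hydrogen (-0.07), and both medians turned positive with median centring (0.08 and 0.13).

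The next comparison asked which genes were altered at both times and whether the strain difference itself changed. CAC0860 and CAC0863 rose at both times, and the change at 48 h less that at 24 h was -2.58 and -3.16 (adjusted p of the difference = 0.00226 and 0.00325). CAC2951 had changes of -3.49 at 24 h and -2.95 at 48 h, and the difference did not pass (0.54; adjusted p = 0.22). CAC0078 had changes of 2.55 and 1.92, with a difference of -0.63 (adjusted p = 0.514). By contrast CAC3680 rose at 24 h and had a change of -0.83 at 48 h (difference -4.13; adjusted p = 0.000897), and CAC3362 rose at 48 h and had a change of -1.80 at 24 h (difference 4.79; adjusted p = 0.000669). Of the 54 genes named in either strain comparison, 33 had a strain difference that changed by this test. Over all tested features it was 1223 of 3859 (31.7%). Most of the 54 were named for their change at 24 h or 48 h, values that this test reuses. Their higher share is therefore no separate evidence.

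A total of 197 features were called at both times, against 131.5 expected of independent lists, 142 in the same direction and 55 in opposite ones. Features lower at both times numbered 123 against 41 expected (Fisher's exact test, two-sided, p = 2.44e-34), features higher at both 19 against 17 (p = 0.591), features higher and then lower 23 against 62.2 (p = 3.44e-10) and features lower and then higher 32 against 11.2 (p = 1.49e-08), for 4 overlaps tested on features that are not independent. The number higher at both was 10 without control 48 h replicate 2, 13 without overexpression 24 h replicate 2 and also without overexpression 48 h replicate 1, 28 without overexpression 48 h replicate 2 and 29 without control 48 h replicate 1. With quantile normalization 31 were higher and 108 lower at both times, and after centring on spike-ins 96 and 67. Without control 48 h replicate 2, 128 features were called at both. The strain effects at 24 h and 48 h correlated across features at r = 0.145 (Spearman's rho = 0.118), features not being independent replicates, at r = 0.083 and 0.085 without overexpression or control 48 h replicate 2, and at r = 0.192 and 0.193 without overexpression or control 48 h replicate 1. The series' design text states 691 and 424 altered genes at 24 h and 48 h and 153 at both, at a 2-fold limit. With 2-fold as the limit and no p-value, the scanner values gave 1105, 593 and 261. The authors' value table, an alternative chosen after the data were seen, gave 967, 508 and 247. These counts at both times include opposite directions. Higher and lower at both were 23 and 143 with the scanner values, and 30 and 119 with the authors' table. The scanner counts also include CEA and unnamed features, which that table lacks.

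The strain difference changed in 1223 features between 24 h and 48 h, 343 more positive and 880 more negative at 48 h. After centring on the median the split was 593 and 398, with quantile normalization 481 and 549, with the authors' processed values 424 and 542, and after centring on spike-ins 388 and 359, out of 747. Without overexpression 24 h replicate 1 the number more negative was 581. The median change over all features was -0.39 with the 75th percentile and 0.08 with the median. Of 9 arginine synthesis genes 8 became more positive and 1 more negative (camera adjusted p = 0.00017), of 6 branched-chain genes 5 became more positive (4.45e-06) and of 7 purine genes 6 (4.03e-05). Of 16 heat shock genes 11 became more negative (camera adjusted p = 0.00032), and of 7 oxygen and peroxide defence genes 4 more positive (0.000233). Fatty acid synthesis (2 of 12 more positive; camera adjusted p = 0.00453), phosphate uptake (4 of 7 more negative; 0.0363), histidine synthesis (none of 9 called; 0.00617) and sulfate and cysteine assimilation (none of 9 called; 0.023) also passed. Adjusted over the list alone the changed members numbered 9 arginine, 5 branched-chain, 6 purine, 11 heat shock, 6 oxygen, 2 fatty acid, 4 phosphate, 0 histidine and 0 sulfate genes. With an estimated correlation the adjusted p was 0.487 for arginine, branched-chain, purine, heat shock, oxygen and phosphate, 0.642 for fatty acid, and 0.649 for histidine and for sulfate. By fry the branched-chain, phosphate and heat shock lists passed (adjusted p = 0.00754, 0.00754 and 0.00827). The purine, oxygen, arginine, fatty acid, histidine and sulfate lists did not pass by fry (0.06, 0.0611, 0.117, 0.173, 0.34 and 0.461). The phosphate list was lost without any of 4 arrays (overexpression 24 h replicate 2, overexpression 48 h replicate 1, control 24 h replicate 1 and control 48 h replicate 2; camera adjusted p from 0.0547 to 0.0795), the histidine list without control 48 h replicate 2 (0.0803) and with quantile normalization (0.0854), and the sulfate list without overexpression 48 h replicate 1 (0.155), control 24 h replicate 1 (0.0721) or control 48 h replicate 1 (0.206), with median centring (0.226) and with quantile normalization (0.117). Under normexp the phosphate list was also lost (camera adjusted p = 0.128). The 8 lists that did not pass had camera adjusted p of 0.143 for solvent formation, 0.189 for pyruvate and hydrogen, 0.634 for sporulation regulators, 0.904 for ATP synthase, 0.58 for agr, 0.0735 for tryptophan synthesis, 0.398 for cellulosome and 0.196 for the megaplasmid. The last passed under normexp (camera adjusted p = 0.0419). The tryptophan list passed without overexpression 24 h replicate 1 (camera adjusted p = 0.00207), overexpression 48 h replicate 2 (0.0175) or control 24 h replicate 2 (0.0338), and with median centring (0.0102) or quantile normalization (0.0255). Camera directions were up for sporulation regulators and ATP synthase with medians of -0.17 and -0.11, which turned positive with median centring (0.31 and 0.37).

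In the control strain between 24 h and 48 h, large rises were those of CAC0659 (34.2-fold), CAC0658 (25.8-fold), the potassium transport gene CAC3680 (24.3-fold), and CAC3273 (51.3-fold) and CAC3676 (32.4-fold), with adjusted p from 5.35e-05 to 0.000638. CAC1043 was not well above background on either control 24 h array and was at least 19.9-fold higher at 48 h (adjusted p = 0.000932), while CAC3273 and CAC3676 were well above it on 1 of the 2, so their folds rest on a dim array. The order of the rises depended on the background: under normexp CAC3680 was the largest of these 6, and the others were at 2.88 for CAC3273, 2.55 for CAC0659, 2.35 for CAC3676, 3.30 for CAC0658 and 1.97 for CAC1043, against 5.68, 5.09, 5.02, 4.69 and 5.21. Without control 48 h replicate 1 or 2 CAC3273 was at 4.99 and 6.37, CAC0659 at 4.43 and 5.76 and CAC0658 at 4.01 and 5.37, and without control 24 h replicate 1 or 2 CAC1043 was at 5.98 and 4.45. CAC1131, CAC1133, CAC1109 and CAC1135 were not well above background on either control 48 h array and were at least 9.94-fold, 11-fold, 9.19-fold and 2.94-fold lower there (adjusted p = 0.00496, 0.00577, 0.00675 and 0.00317). Under normexp background correction these 4 changes were 0.07, 0.10, 0.12 and 0.48, and none passed. The median change over all tested features was 0.38 there, so their signs do not show a reversal. CAC2389 and CAC2388 of arginine synthesis fell by 14.5-fold and 11.5-fold (adjusted p = 0.029 and 0.0379); without control 24 h replicate 2 their changes shrank from -3.86 and -3.52 to -2.42 and -1.93 (adjusted p = 0.146 and 0.178), and without control 24 h replicate 1 they were -5.29 and -5.12. Without control 48 h replicate 1 the adjusted p was 0.112 and 0.134, and without control 48 h replicate 2 it was 0.0892 and 0.107. CAC2388 was also lost without overexpression 24 h replicate 1 or 2 (adjusted p = 0.0576 and 0.0589). Neither gene passed under normexp (adjusted p = 0.145 and 0.147) or with a trended and robust prior (0.103 and 0.122).

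Of 812 features called for age in the control strain, 433 rose and 379 fell; after centring on the median 307 rose and 501 fell, and after centring on spike-ins 702 and 242. Of 12 sporulation regulators 7 rose (camera adjusted p = 0.0123), of 7 phosphate uptake genes 5 rose (0.00138) and of 16 heat shock genes 2 rose (0.0153). Of 7 oxygen and peroxide defence genes 4 fell (camera adjusted p = 0.00138), of 6 branched-chain genes 5 fell (0.00138), of 12 fatty acid genes 1 fell (0.00138), of 9 arginine genes 6 fell (0.0153), of 7 purine genes 2 fell (0.0299) and of 9 histidine genes none passed (0.0299). Adjusted over the list alone the counts were 7, 5, 2, 4, 5, 1, 8, 2 and 0 in that order, and with an estimated correlation each of these 9 lists had an adjusted p of 0.653. Without control 24 h replicate 1 the sporulation and heat shock lists were lost (camera adjusted p = 0.0928 and 0.0939), without control 24 h replicate 2 the arginine, histidine and purine lists (0.101, 0.244 and 0.372), and without control 48 h replicate 2 the heat shock, histidine and purine lists (0.0841, 0.409 and 0.123). Median centring also ended the arginine, histidine and purine calls (0.0528, 0.0725 and 0.0729), and quantile normalization those of histidine and purine (0.114 and 0.0903). Without control 24 h replicate 2 the ATP synthase, cellulosome and megaplasmid lists passed (camera adjusted p = 0.025, 0.0314 and 0.0481), and without control 48 h replicate 2 the sulfate list (0.0131). With quantile normalization ATP synthase and cellulosome passed (camera adjusted p = 0.016 and 0.0245).

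In the overexpression strain 595 features were called for age, 140 higher and 455 lower at 48 h; after centring on the median 260 were higher and 256 lower, with quantile normalization 218 and 273, with the authors' processed values 174 and 269, and after centring on spike-ins 474 and 158. Without overexpression 24 h replicate 2 the number higher was 89. Of 12 sporulation regulators 5 rose (camera adjusted p = 3.44e-05), of 6 branched-chain genes 5 rose (2.59e-05), of 7 purine genes 6 rose (2.59e-05), of 9 arginine genes 1 rose (0.00147) and of 9 sulfate and cysteine genes none passed (0.0147). Of 16 heat shock genes 6 fell (camera adjusted p = 0.00382), of 7 tryptophan genes 5 fell (0.0182), of 10 cellulosome genes 3 fell (0.00836), and among 163 megaplasmid genes 39 fell and 5 rose (0.00735). Adjusted over the list alone the counts were 5, 5, 6, 5, 0, 6, 7 and 3, then 39 and 7. With an estimated correlation each of these 9 lists had an adjusted p of 0.671. The tryptophan list was lost without overexpression 24 h replicate 2 (camera adjusted p = 0.0526) or overexpression 48 h replicate 1 (0.133), the sulfate list without the latter (0.272), with median centring (0.214) and with quantile normalization (0.121), and the cellulosome list under normexp (0.246). The lists that did not pass for age had camera adjusted p of 0.0776 to 0.824 in control and 0.0882 to 0.951 in the overexpression strain. In the overexpression strain ATP synthase passed without overexpression 24 h replicate 1 (camera adjusted p = 0.0339) or overexpression 48 h replicate 1 (0.0263), and with quantile normalization (0.0131), median centring (0.0489) and normexp (0.00963). Histidine synthesis passed under normexp (camera adjusted p = 0.044), oxygen and peroxide defence without overexpression 24 h replicate 1 (0.0271) and phosphate uptake without overexpression 24 h replicate 2 (0.0303). The pyruvate and hydrogen median was 0.01 in control with a camera direction of down and -0.11 in the overexpression strain with a direction of up, and with median centring the medians were -0.14 and 0.21.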

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

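Chosen only after the results were seen were the simulations of shared control arrays, the covariance over bright features, the comparisons of the control 24 h arrays and of sporulation regulators, the tests on CAC0860 and CAC0863, and the use of median and spike-in centring to weigh the lean of the calls. The tests of the changed strain difference, r over bright features and the share of rises among brighter features were set before.

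The strain difference changed between 24 h and 48 h in 1223 features by the test of the difference itself (limma). Under normexp the number was 181. Of the 54 genes named in the strain comparisons 33 were among the 1223, 17 more positive and 16 more negative at 48 h. Over all 3859 tested features the share was 31.7%, and most of the 54 were named for a change at 24 h or 48 h that this test reuses. The differences, 48 h effect less 24 h effect on the log2 scale, were 6.84 for CAC2389, 6.46 for CAC1133, 6.45 for CAC2388, 5.57 for CAC1109, 4.91 for CAC3618, 4.79 for CAC3362, 4.12 for CAC2645, 3.89 for CAC1394, 2.84 for CAC3174 and 2.69 for CAC3171. They were 2.26 for CAC3657, 2.16 for CA_P0128, 1.92 for CAC2449, 1.90 for CAC0028, 1.84 for CA_P0058, 1.66 for CAC3205 and 1.18 for CAC3575. In the other direction they were -5.89 for CAC3617, -4.69 for CAC3157, -4.59 for CAC0608, -4.44 for CAC3158, -4.16 for CA_P0077, -4.13 for CAC3680, -4.12 for CA_P0102, -4.04 for CAC3681, -3.16 for CAC0863 and -2.58 for CAC0860. The smaller ones were -2.50 for CAC3190, -2.38 for CAC2433, -2.19 for CAC1705, -2.12 for CA_P0164, -1.90 for CA_P0165 and -1.35 for CAC2071. CAC1133 was not well above background on any overexpression 24 h or control 48 h array, nor CAC1109 on either control 48 h array. Under normexp neither was called at 48 h. The control 24 h SDs of CAC2389 and CAC2388 were 2.03 and 2.26. With an estimated correlation no list passed (adjusted p of at least 0.487). The list medians of this difference, for the 9 lists past the camera test with its preset correlation, were 4.12 for arginine, 2.98 for purine, 2.77 for branched-chain, 1.86 for sulfate and cysteine, 1.11 for oxygen and peroxide, 0.95 for histidine and 0.28 for fatty acid genes, and -1.32 for heat shock and -1.14 for phosphate uptake genes.

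The strain effect at 24 h resembled the age effect in control, with which it shares the control 24 h arrays: across features r was 0.797 and the covariance 0.749. In 100 simulations with no effects, drawn from the spread between the arrays of a group, r was 0.502 on average and at most 0.61. The simulated covariance was 0.058 on average and at most 0.074, so the spread between arrays does not account for the covariance of 0.749. A departure common to both control 24 h arrays was not simulated, so it is not excluded. Of the calls, 320 were higher in both against 69.5 for independent lists, and 245 lower in both against 40.1. Part of this overlap may come from the shared arrays. Over the brightest 1286 features r was 0.77, which decides nothing since simulations reached 0.637 there, but the covariance of 0.668 against a simulated highest of 0.09 argues against dim features. The control 24 h arrays correlated with other groups at no more than 0.939 on average, and since no other group lay in their 2 places on the slide, their handling and a difference of the control cultures cannot be told apart. A candidate explanation, that overexpression cultures were further along the culture course at 24 h, stays open. Of the 7 sporulation regulators that rose with age in control, 2 were called higher in the overexpression strain at 24 h. In features called with age in control, the strain effect at 24 h reached a median share of 0.934 of the age effect. Both effects were measured from the same control 24 h arrays. The age effects in control and in the overexpression strain correlated across features at r = 0.084.

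CAC0860 and CAC0863 rose far above other called features at both times. The tags numbered between them rose by a median of 1.338 at 24 h and 0.963 at 48 h on the log2 scale, which argues against 1 amplified or read-through stretch over both. Rises of that size at 24 h were not limited to these tags: CAC0858 and CAC0859 had changes of 1.656 and 1.65. At 48 h the latter 2 had changes of -0.047 and -0.103. The lowest change of the pair under the alternatives run was 6.524, with 0 of 4 calls lost, which argues against the handling of dim control spots. That both are the genes carried by the overexpression construct is a hypothesis that stays open: the 2 features above 5 log2 units at both times only restate the pattern, and the sources used here do not tie btrK or btrR to these tags.

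With the 75th percentile, calls leaned to rises at 24 h (60.3%) and to falls at 48 h (21.5% rises). The shares of rises were 51.7% and 41.8% with quantile normalization, and 53% and 37.2% with the authors' table. Quantile normalization gives all arrays the same distribution, so its shares cannot decide the cause. In the authors' table the column medians were 7.88 to 7.95 and the maxima 16.57 to 16.63, while the scanner medians were 7.24 to 8.73. Its columns were thus also made alike, by a normalization that is not given, and its shares cannot decide the cause either. Dim features are argued against, since the shares of rises among the brighter features were 61.5% and 25.1%. Centring on the median moved the shares to 37.4% and 41.4%, and centring on spike-ins to 72.6% and 71.1%, but a new centre adds 1 constant per array to all features and moves the shares whatever the cause. Scaling to the 75th percentile and unequal messenger per cell or unequal RNA input therefore cannot be told apart as sources of the lean. No biological explanation of the lean was tested.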

How the results depend on the processing

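The alternatives with only CAC and CA_P features, with the authors' table at 2-fold alone and with spike-in centring were chosen after seeing the data, and the others before. Of 57 called results for named genes, 26 lost their call under at least 1 alternative, and of 88 results for named genes, called or not, 54 never changed their call. The 42 sign changes of values that were not called are listed below with those of called ones. Signal over background limits the dimmest probes. The lowest count of calls in each contrast came under normexp, which sets another background. Some calls were lost there though the change hardly moved. At 48 h CAC3174 was at 1.095 against 1.078, and at 24 h CAC2388 was at -3.273 against -3.472 and CAC0938 at -1.287 against -1.36. Others shrank, such as CAC3362 at 48 h, to 0.584 from 2.997. With 1 array left out, the lone array of its group is assumed to vary like the other groups. Unless a reason is given, the cause was not tested.

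Under normexp the counts were 326 at 24 h, 156 at 48 h, 181 for the changed strain difference, 239 for age in control, 178 for age in the overexpression strain and 41 at both times, and 10 lists passed at 48 h. With adjusted p and no fold limit, a wider rule by construction, the counts were 1928 at 24 h, 896 at 48 h, 1576 and 1093 for age in control and overexpression, and 496 at both times. Centring on spike-ins gave 747 for the changed strain difference. With an estimated correlation in camera 0 lists passed in each of the 5 contrasts. Fry passed 6 at 24 h, 4 up and 2 down, among them solvent formation and heat shock, which camera did not pass. It passed 1 at 48 h (heat shock) and 3 for the change (branched-chain, phosphate and heat shock). For age it passed 6 in control and 4 in the overexpression strain.

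Leaving out 1 array at a time gave 292 to 518 calls at 48 h, 128 to 220 at both times, a correlation of strain effects of 0.083 to 0.193 and 4 to 10 lists at 48 h. The 24 h counts stayed between 797 and 1275, which is within 1.5 times. For histidine synthesis at 48 h the camera adjusted p ranged from 0.0044 to 0.808 and the direction turned. Changes that turned sign ranged at 24 h from -0.055 to 0.331 for CAC1694, -0.488 to 0.482 for CAC3152 and -0.205 to 0.238 for CA_P0163, and at 48 h from -0.301 to 0.712 for CAC1696, -0.378 to 0.377 for CAC2306, -0.108 to 0.725 for CAC2307, -0.208 to 0.148 for CAC2859, -0.374 to 0.01 for CAC3152 and -0.276 to 0.113 for CAC3392.

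With quantile normalization the 48 h changes that turned sign were 0.023 for CAC2306, 0.331 for CAC2859 and 0.017 for CAC3392. With median centring they were -0.252 for CA_P0163 and -0.13 for CAC1694 at 24 h, and 0.01 for CA_P0165, 0.206 for CAC2306, 0.176 for CAC2859, 0.024 for CAC3152 and 0.124 for CAC3392 at 48 h. Under normexp they were -0.001 for CA_P0163 and 0.08 for CAC3152 at 24 h; -0.541 for CAC1109, -0.666 for CAC1133, -0.245 for CAC1694, -0.625 for CAC1696, 0.013 for CAC2306 and -0.009 for CAC3205 at 48 h; and 0.124 for CAC1109, 0.073 for CAC1131, 0.095 for CAC1133 and 0.482 for CAC1135 with age in control. The median change over all tested features under normexp was 0.15 at 24 h, -0.49 at 48 h and 0.38 with age in control. In the authors' table the changes that turned sign were 0.021 for CAC3152 at 24 h, and 0.03 for CA_P0163 and 0.299 for CAC2859 at 48 h. After centring on spike-ins they were 0.161 for CAC3152 at 24 h, and 0.091 for CA_P0163, 0.298 for CA_P0165, 0.025 for CAC2071, 0.494 for CAC2306, 0.464 for CAC2859, 0.312 for CAC3152 and 0.413 for CAC3392 at 48 h.

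With the replicate number as a block the counts were 1031 at 24 h, 499 at 48 h, 1246 for the change, 810 and 606 for age and 199 at both times. The block ended the call of CAC2388 with age in control (adjusted p = 0.0516) and brought the tryptophan list past the test for the change (0.00282). Same-numbered arrays' deviations correlated at -0.212 to 0.2, so the numbers were not taken to pair the arrays. The brightest-probe and slide or scan alternatives were not run, since each gene name has 1 probe and there was 1 slide and 1 scan.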

Other observations

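The runs of tags below and their test were chosen after the values were seen.

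Called features lay in stretches of neighbouring locus tags. At 24 h the 13 tags from CAC2007 to CAC2019 rose together in the overexpression strain, with a median change of 1.56 and a range of 1.22 to 2.41. The 8 tags from CAC3675 to CAC3682, a stretch that holds the kdp potassium transport genes, rose with a median of 2.68. Falls came in stretches too, with 12 called features from CAC3634 to CAC3646 (median -2.63), 9 from CAC2585 to CAC2593 (median -2.38) and 8 from CAC2147 to CAC2154 (median -1.46).

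At 48 h the 12 tags from CAC3047 to CAC3058 fell together with a median of -1.57, and 5 from CAC0014 to CAC0018 fell with a median of -3.42. The 8 tags from CAC2585 to CAC2592 were called lower again (median -2.28), as were 6 called features from CAC2951 to CAC2959 (median -2.47), of which CAC2951 to CAC2955 were also called lower at 24 h.

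The hypothesis that neighbouring tags are called together, as genes of shared transcripts would be, was tested by shuffling the order of the tags. Of 914 called CAC features at 24 h, 276 lay in 53 runs of at least 4 consecutive measured tags with the same direction, against a mean of 9.7 and a highest of 38 in 1000 shuffles. At 48 h it was 111 of 423 in 21 runs, against a mean of 1.4 and a highest of 13. The order of the tags is therefore not unrelated to the calls; which runs are operons was not tested.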
